A study of Mus musculus with 313 samples.

How the data were processed

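Multiplex quantitative RT-PCR was run on single sorted cells with a microfluidic Biomark HD system and 100 assays. Per the labels, cells of embryonic day 15 fetal liver were reverse transcribed and preamplified for 22 cycles before loading. The labels' protocol describes TaqMan or Solaris assays, while the label field names SYBR Green. Which assay used which chemistry is not given in the sources used here. The values the authors deposited are raw Ct values, per the file headers, with no normalization. A Ct is the PCR cycle at which fluorescence crosses a threshold, so that 1 cycle less stands for about 2 times as much cDNA. Cells without a Ct for an assay are entered as missing, and the rule behind a missing value is not given in the sources used here. The series text speaks of 339 sorted cells (157 aLP, 168 ILCP and 14 LTiP) and of 299 cells after filtering by housekeeping expression. The table used here holds 313 cells, of which 147 are aLP, 152 ILCP and 14 LTiP. The aLP and ILCP cells together number 299.

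Groups were taken from the labels. The series text speaks of 2 independent sorts of pooled fetal livers, and each cell name carries the number 2 or 3. This number was taken as the sort, although no label defines it. The replicate was the pool of cells of 1 group and 1 sort, and cells were not counted as replicates. The p-values therefore rest on the spread between 2 pools per group, moderated toward the spread of the other assays, and the sorts of these pools may differ in technical ways. Cells of sort 2 fell into number ranges: all 55 aLP cells were numbered 97 or higher, as were 10 of the 62 ILCP cells. LTiP cells came from sort 3 only, and all 14 were numbered 1 to 96.

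A gene counted as detected in a cell with a Ct below 24. The level was 24 minus the Ct, or 0 where the gene was not detected, and a pool's value was the mean over all its cells. A difference of such means is in cycles and mixes the share of detecting cells with the amount in them, so it is not a fold. Of 11450 Ct values, 447 (3.90%) lay at or above 24, among them 129 of 215 for Id2 and all 31 for Il1r1. The values ran from 2.51 to 40.5. The lowest was 1 Hprt value in an ILCP cell of sort 3, and the next lowest Hprt Ct was 13.2. Cells were kept with at least 1 of the 4 housekeeping assays (Actb, Gapdh, Hprt and Tbp) and at least 5 assays detected, which left out 1 aLP cell of sort 2 with 2 assays. No per-cell normalization was applied. No 2 cells had identical profiles. Assay names were matched to a mouse gene table of assembly GRCm38.p6, with 98 matched by symbol, 1 (Aes) by synonym and 1 (Pira11) unmatched and kept as given.

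Assays detected in at least 5% of the cells of at least 1 of the 4 aLP and ILCP pools were tested, which left 91 of 100. An assay silent in 1 sort and detected in over 10% of the cells of the other was to be left out. ILCP was compared with aLP with limma (version 3.58.1 in R 4.3.3; lmFit and eBayes) on the 4 pool values, with group as the only term, Benjamini-Hochberg adjustment and a threshold of 0.05. The fit with the sort as a block was an alternative. The deviations of same-numbered aLP and ILCP pools from their group means had a correlation of -0.047. Of 15 gene groups fixed beforehand, the 12 with at least 3 tested assays were tested with fry, adjusted over the groups. Camera with an estimated correlation was an alternative. LTiP was compared within sort 3 as differences of shares, without a test in the main comparison. A limma fit over all 5 pools, with or without the sort as a block, was an alternative. Random lists for percentiles were drawn 10000 times from the assays of the panel, matched on mean level. Shares carry exact Clopper-Pearson 95% intervals. A share of 0 in aLP or ILCP cells carries the upper limit of 3 cells over the number of cells, and one in LTiP cells its exact interval. Both cover counting error only and limit cells with a detected transcript, not cells that express the gene. Figures were drawn with Python 3.11.15, pandas 2.3.3 and matplotlib 3.10.9.

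The rule for named genes was fixed before the data were examined. It took up to 12 called assays in each direction with the same sign in both sorts and filled the list to 24 with assays that did not pass, by size. It took the 10 largest differences of share in each direction for LTiP against each other group. It added gate genes, housekeeping genes, genes of the fixed pairs and up to 4 examples per group. Of 14 fixed pairs, 13 had both assays on the panel. Values of 2 assays, alone and in pairs, are not reported here, while both stayed in the fits and group values, though not among the genes used to mark ILCP cells.

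Alternatives varied the detection limit (22, 26, 28 or none), scaling to housekeeping assays or to each cell's median, the cell and assay filters, the way cells were averaged, the number range of cells, the block, weights by cell number, and the pools included. Others, chosen after the data had been seen, required Actb, Gapdh and Hprt, scaled on these 3, matched cells on their Ct in bins of 0.5 cycles, or left out aLP cells with Zbtb16. The test was tried on simulated data with 20 of 91 assays changed in each of 100 runs. Without the block, 46.9% of changes of 2 cycles and 73.2% of changes of 4 cycles were recovered, with 0.04 and 0.06 false calls per run. With the block, 66.6% and 92.2% were recovered, with 0.14 and 0.33 false calls. For the group test 62.0% of groups shifted by 2 cycles were called, and 0.117% of unshifted ones. Each simulated ILCP pool was drawn from the aLP cells of its own sort, so both groups shared the full sort effect. The data did not show such sharing (correlation of -0.047), so these rates, above all those with the block, need not hold for them. Shifts were also added whole to the pool means of assays drawn at random. Decreases could thus reach levels below 0, which the measure cannot give.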

Results

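Single precursor cells from the livers of mouse fetuses at embryonic day 15 were profiled with 100 quantitative RT-PCR assays for genes of lymphoid development. At this stage the fetal liver holds the precursors of innate lymphoid cells (ILCs), lymphocytes without rearranged antigen receptors, and of lymphoid tissue inducer (LTi) cells, which start the formation of lymph nodes and Peyer's patches. All cells had been sorted as lineage-negative and positive for the interleukin-7 receptor α chain and integrin α4β7. Cells with neither PLZF nor CXCR5 were the α4β7+ lymphoid precursors (aLP), PLZF-positive cells were the ILC precursors (ILCP), and PLZF-negative CXCR5-positive cells were the LTi precursors (LTiP). PLZF is the protein of Zbtb16, and CXCR5 is the receptor for the chemokine CXCL13. Each cell carried the number 2 or 3 in its name, taken here as the sort. The 5 pools of cells made in this way were aLP of sort 2 (55 cells, 54 after filtering) and sort 3 (92 cells), ILCP of sort 2 (62 cells) and sort 3 (90 cells), and LTiP of sort 3 (14 cells).

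The number of assays detected per cell differed between the groups. An ILCP cell gave 40.8 ± 0.041 detected assays and an aLP cell 30.2 ± 2.81 (mean ± SD of pool means, n = 2 pools each). The mean was 32.2 in aLP cells of sort 2 and 28.2 in those of sort 3, and 33.6 in LTiP cells. The medians were 41 in both ILCP pools, 36.5 and 28 in the aLP pools of sorts 2 and 3, and 34.5 in LTiP, so that the gap in sort 2 was smaller by medians than by means. The housekeeping assays Actb and Gapdh were detected in every cell used. The mean Hprt Ct was 16.2 and 16.3 in the ILCP pools of sorts 2 and 3, against 16.9 and 17.6 in the aLP pools and 17.7 in the LTiP pool. The ILCP mean of sort 3 includes 1 Ct of 2.51. The mean Actb Ct was 12.3 in ILCP and 13.3 in aLP in sort 2, but 12.7 in ILCP and 12.6 in aLP in sort 3. A lower Ct means more cDNA.

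The comparison of ILCP with aLP asked which factors distinguish precursors with PLZF from those that lack it. The transcription factor genes Tcf7, Rora and Ets1 and the retinoid X receptor gene Rxrg were higher in ILCP in both sorts, and Irf8, a transcription factor gene of myeloid, dendritic and B cells, was lower. Tcf7, which acts early in T cells and ILCs, was detected in 88.7% and 96.7% of ILCP cells in sorts 2 and 3, against 31.5% and 17.4% of aLP cells. Rora, needed for group 2 ILCs, was detected in 74.2% and 78.9% of ILCP cells, against 11.1% and 2.2% of aLP cells. For Ets1 the shares were 77.4% and 75.6% in ILCP and 29.6% and 30.4% in aLP. Rxrg was detected in 38.7% and 35.6% of ILCP cells, in 1.85% of aLP cells of sort 2 and in 0 of 92 aLP cells of sort 3, which allows a share of up to 3.3%. Irf8 was detected in 74.1% and 79.3% of aLP cells and in 40.3% and 33.3% of ILCP cells.

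On the scale of cycles above the detection limit, averaged over all cells of a pool, Tcf7 stood at 7.09 ± 0.82 in ILCP and 1.47 ± 0.64 in aLP (SD, n = 2 pools each). The difference was 5.62 ± 0.58 (SE, here and below moderated by limma over all assays), with 4.59 in sort 2 and 6.66 in sort 3. The Rora difference was 4.83 ± 0.31, with 4.41 and 5.24 in the sorts. Ets1 differed by 3.60 ± 0.38 (3.99 and 3.2) and Rxrg by 2.21 ± 0.23 (2.23 and 2.2). Irf8 differed by -2.88 ± 0.31 (-2.45 and -3.31). Zbtb16, which encodes the protein the gate selects on and so is no finding, differed by 7.10 ± 0.43 (6.41 and 7.80). In limma with Benjamini-Hochberg adjustment over 91 assays, the adjusted p was 0.00615 for Zbtb16 and Rora and 0.0138 for Tcf7, Ets1, Rxrg and Irf8. These 6 assays, 5 higher and 1 lower in ILCP, were all that passed, and 27 had an unadjusted p under 0.05. With cells scaled to their housekeeping assays 5 higher and 0 lower passed, and with cells scaled to their median assay 5 and 2. The housekeeping scaling includes Tbp, which gave no Ct in any aLP cell of sort 2. Scaled on Actb, Gapdh and Hprt alone, a setting chosen after the data had been seen, 7 higher and 2 lower passed, Irf8 among them. With the sort as a block in the fit, 2 assays passed: the adjusted p was 0.0458 for Zbtb16 and Rora and 0.0611 for the other 4. Leaving out a pool leaves 1 group with 1 pool. The spread of an assay, before moderation over assays, then comes from the 2 pools of the other group alone, and the counts are not comparable with that of the full fit. Without the ILCP pool of sort 2 or that of sort 3, 0 assays passed in limma (19 and 23 at an unadjusted p under 0.05), and without the aLP pool of sort 2, 20 passed. The count was 11 to 17 with higher detection limits, a 20% assay filter or levels averaged on a linear scale, and 20 with shares of detected cells. It was 0 with detected cells only, where Zbtb16, Rora and Rxrg had too few detecting aLP cells to be tested.

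**Figure D1:**
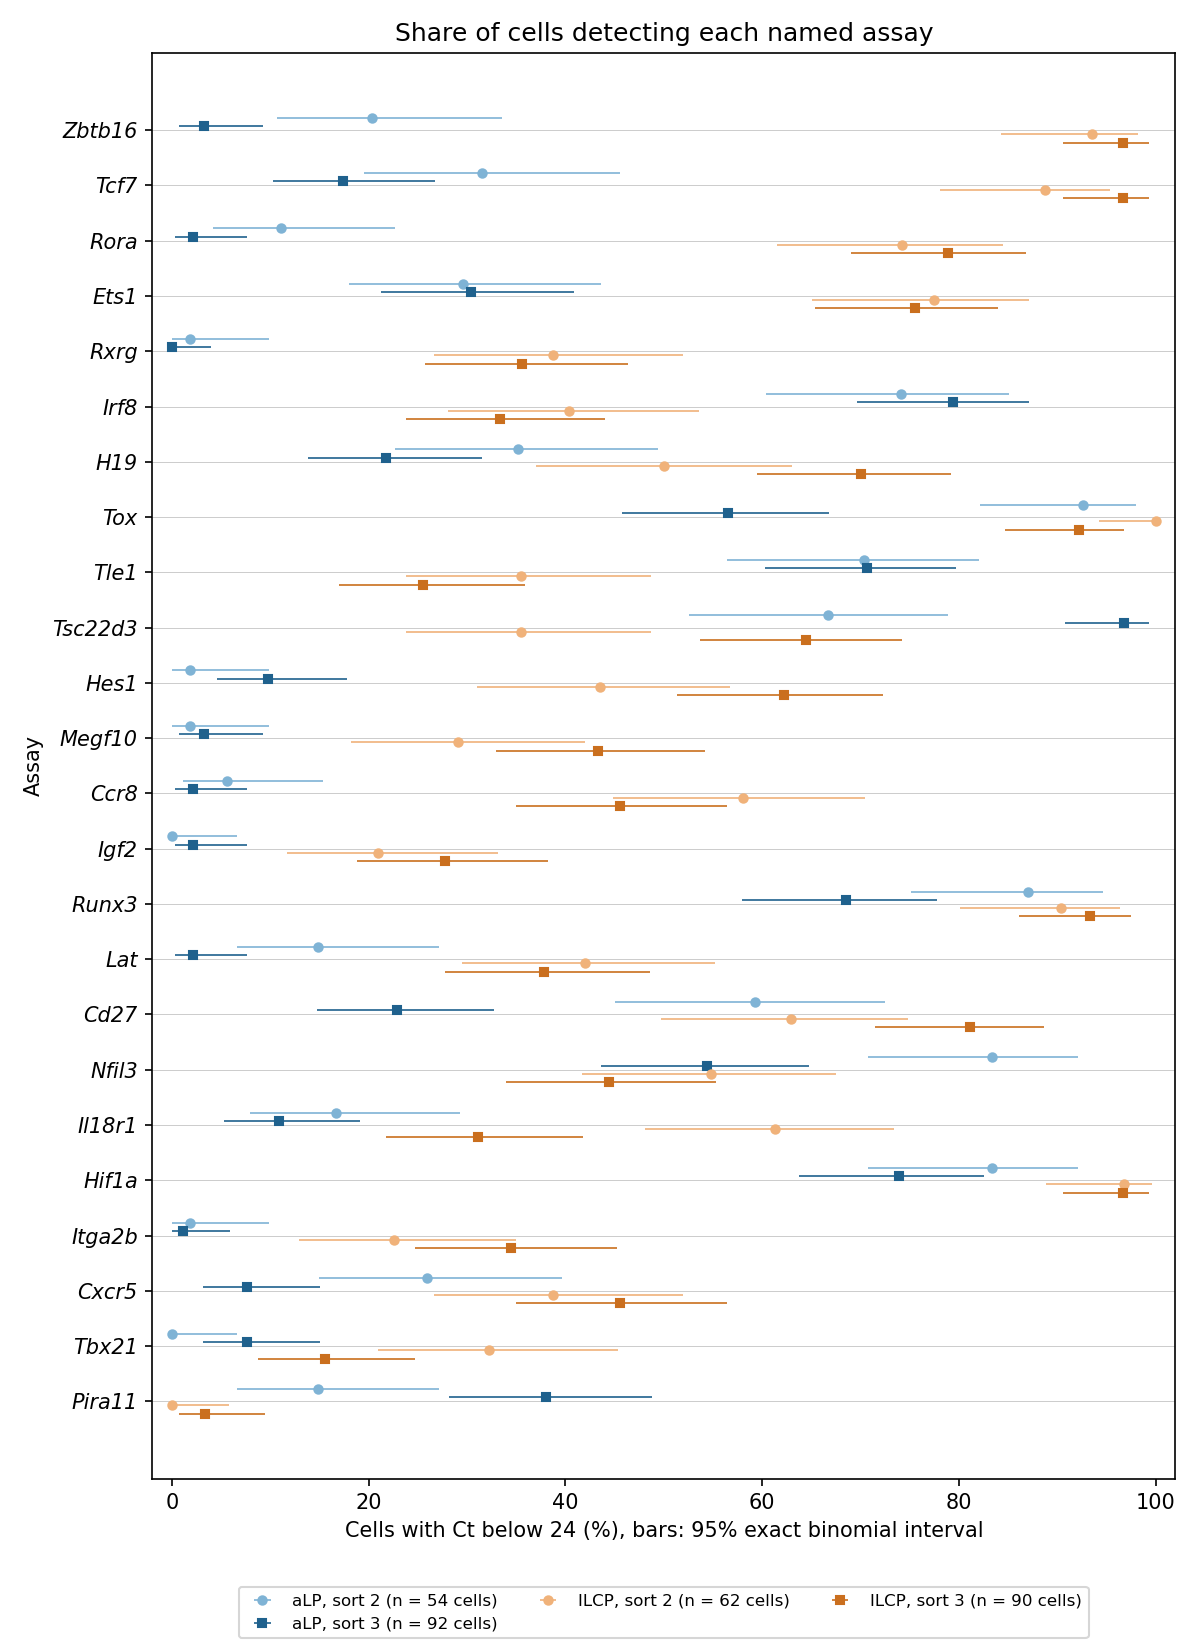
Percent of cells with a Ct below 24 for the 24 assays named for ILCP against aLP, in the aLP and ILCP pools of sorts 2 and 3. Points are pool shares and bars 95% exact binomial intervals, which cover counting error only. For Tcf7 the ILCP pools lie at 88.7% and 96.7% and the aLP pools at 31.5% and 17.4%.

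Among the 18 further assays named by size, none passed the test, and their values follow. The long noncoding RNA H19 differed by 2.57 ± 0.73, with 1.26 in sort 2 and 3.88 in sort 3. Insulin-like growth factor 2 (Igf2) differed by 1.83 ± 0.35 and was detected in 21.0% and 27.8% of ILCP cells, against 0 of 54 (up to 5.56%) and 2.2% of aLP cells. Hes1, a target gene of Notch signalling, was detected in 43.5% and 62.2% of ILCP cells and in 1.85% and 9.78% of aLP cells. The co-repressor gene Tle1 was detected in 35.5% and 25.6% of ILCP cells and in 70.4% and 70.7% of aLP cells. For both Hes1 and Tle1 the adjusted p was 0.0685. The chemokine receptor gene Ccr8 was detected in 58.1% and 45.6% of ILCP cells and in 5.56% and 2.2% of aLP cells (adjusted p = 0.115). Itga2b, the αIIb integrin gene of megakaryocytes, gave 22.6% and 34.4% in ILCP and 1.85% and 1.09% in aLP. Lat, an adaptor gene of antigen receptor signalling, gave 41.9% and 37.8% in ILCP and 14.8% and 2.2% in aLP. Megf10 gave 29% and 43.3% in ILCP, against 1.85% and 3.3%.

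For other named genes the sorts differed in size. Tox, a factor needed for ILC precursors, differed by 1.02 in sort 2 and 4.09 in sort 3, and Cd27 by 0.053 and 3.02. Runx3 differed by 0.85 and 2.59, Hif1a by 1.09 and 1.83, Il18r1 by 1.98 and 0.94, and Tbx21, the gene of T-bet, by 2.1 and 0.42. On the lower side in ILCP, the glucocorticoid-induced gene Tsc22d3 differed by -1.35 and -3.27, Nfil3 by -2.30 and -0.66, and Pira11 by -0.66 and -1.78. Cxcr5, on which the aLP gate selects, differed by 0.74 and 1.83. Among the gate and housekeeping genes not yet given, Il7r differed by -0.10 and 0.70, Itga4 by -0.20 and 0.62, Actb by 0.97 and -0.065, Gapdh by 0.29 and 0.75 and Hprt by 0.72 and 1.22. Tbp differed by 1.5 and 0.55 and gave no Ct in any aLP cell of sort 2. Cxcr5, Il7r, Itga4, Actb and Gapdh changed sign under at least 1 other processing.

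Gene groups fixed before the data were examined were tested with limma's fry, which asks whether the genes of a group move on balance one way. Of 12 groups tested, 1 passed, the T lineage and Notch genes (11 tested), which were higher in ILCP with an adjusted p of 0.00291. With an estimated correlation (limma's camera) the adjusted p was 0.828, and with the sort as a block it was 0.165. The call was also lost with cells scaled to their housekeeping assays (adjusted p = 0.0952) and in cells matched on their housekeeping Ct (0.104). The scaling includes Tbp, which gave no Ct in any aLP cell of sort 2. Scaled on Actb, Gapdh and Hprt alone, a setting chosen after the data had been seen, the group stayed called (fry, adjusted p = 0.0484). In this group 8 members were higher in both sorts, 2 lower in both (Notch1 and Zbtb7b) and 1 mixed. Of the members 1 was called (Tcf7), and 3 when adjusted over the list alone. Tcf7, Gata3, Bcl11b and Lef1 also belong to the ILC precursor group. Gata3, a factor of T cells and group 2 ILCs, was detected in 37.1% and 30% of ILCP cells and in 11.1% and 0 of 92 aLP cells (up to 3.3%). Bcl11b, a T cell and group 2 ILC factor, was detected in 35.5% and 32.2% of ILCP cells, and in 0 of 54 and 0 of 92 aLP cells (up to 5.56% and 3.3%). Its adjusted p was 0.0701.

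Of the 11 ILC precursor transcription factors tested, 4 were called higher (Zbtb16, Tcf7, Ets1 and Rora), 10 had a positive difference in both sorts and Nfil3 a negative one in both. The group's adjusted p was 0.060, and 6 members passed when adjusted over the list alone. The group's unadjusted p was 0.0139, and 0.0191 without Zbtb16. The ILC2 genes (11 tested, 2 called higher, 6 adjusted over the list alone) and the ILC1 and NK genes (5 tested, 0 called) also had an adjusted p of 0.060. All 5 ILC1 and NK genes had a positive difference in both sorts. Il17rb, a receptor gene for interleukin-25, was detected in 16.1% and 14.4% of ILCP cells and in 0 of 54 and 0 of 92 aLP cells. Il2rb, the receptor β chain shared by interleukins 2 and 15, was detected in 46.8% and 45.6% of ILCP cells and in 22.2% and 21.7% of aLP cells. With the sort as a block the adjusted p was 0.165 for the ILC precursor and ILC2 groups and 0.175 for the ILC1 and NK group. ILCP cells also gave more detected assays per cell, 40.8 against 30.2.

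The remaining groups did not pass. The LTi genes (9 tested, 0 called) had an adjusted p of 0.229. The B lineage genes (5 tested, Irf8 called lower) had an adjusted p of 0.133, and Bcl11a was detected in 4.84% and 2.22% of ILCP cells and in 20.4% and 13% of aLP cells. The early lymphoid progenitor genes (3 tested) had an adjusted p of 0.629, with Rag2 in 14.5% and 12.2% of ILCP cells and in 38.9% and 8.70% of aLP cells. The adjusted p was 0.146 for chemokine receptors (3 tested), 0.229 for cytokine receptors (10 tested), 0.184 for Ikaros, Runx and Sox factors (4 tested), 0.133 for the 4 gate genes and 0.0924 for the 4 housekeeping genes. Among these groups the B lineage genes held a called assay (Irf8), as did the gate genes (Zbtb16), and the others held none. Adjusted over the list alone, 2 chemokine receptors, 1 B lineage gene and 1 gate gene passed, and 0 in the other tested groups of this paragraph. The myeloid and dendritic, the erythroid, megakaryocyte and mast, and the E and Id protein groups had fewer than 3 assays and were not tested. They held Irf8, Itga2b, and Tcf3 with Id2. Id2 was detected in 37.1% and 35.6% of ILCP cells and in 20.4% and 12% of aLP cells, and 60.0% of all its Ct values lay at or above the detection limit.

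The ILCP minus aLP differences of the 2 sorts had the same sign for 73 of 91 assays (80.2%), of which 58 were higher and 15 lower in ILCP. Across assays, which are not independent replicates, Pearson's r was 0.680 and Spearman's rho 0.484. Over both sorts 72 of the 91 mean differences (79.1%) were above 0, with a median of 0.54.

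**Figure D2:**
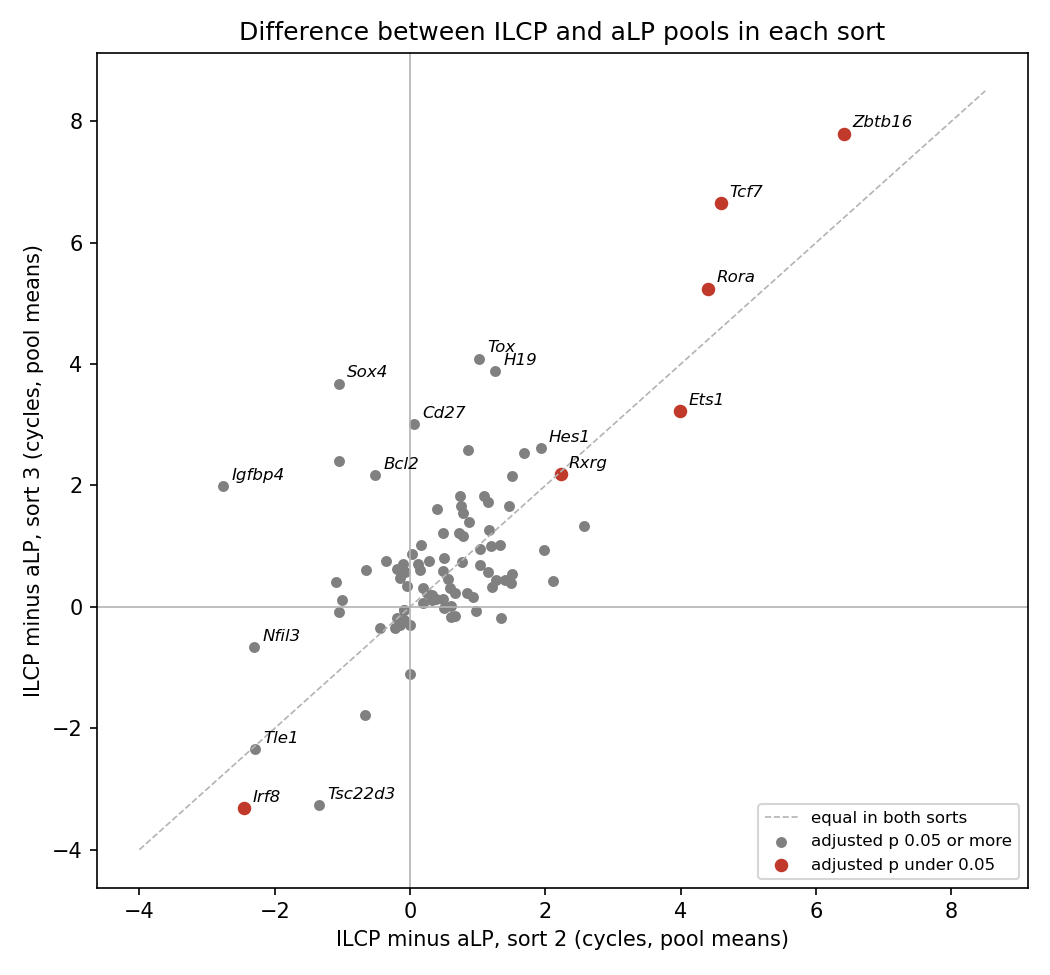
Difference between the ILCP and aLP pool means (cycles) of the 91 tested assays in sort 2 (x axis) and sort 3 (y axis), with the 6 assays at an adjusted p under 0.05 in red. Zbtb16 lies at 6.41 and 7.80 and Irf8 at -2.45 and -3.31, and Igfbp4 lies at -2.77 and 1.98.

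The comparison of LTiP with aLP asked what sets CXCR5-positive precursors apart from those with neither CXCR5 nor PLZF. LTiP had 1 pool, so the main comparison made no test and set the values of sort 3 side by side, with exact binomial intervals that cover counting error only. LTi genes were detected more often in LTiP. Lta, which encodes lymphotoxin α, was detected in 9 of 14 LTiP cells (64.3%, 95% interval 35.1 to 87.2), against 4.35% of aLP cells (1.20 to 10.8). Cxcr5, a gate gene, was detected in 12 of 14 LTiP cells (85.7%) and 7.61% of aLP cells. Over the 11 LTi genes the share of detected cells was on average 29.6 percentage points higher in LTiP, 9 genes being higher and 1 lower, and 24.7 points higher without Cxcr5. Their median difference, 28.6 points, lay at percentile 99.3 among 10000 random lists of that size matched on mean level.

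ILC precursor factors were also detected more often in LTiP than in aLP. Tcf7 and Ets1 were each detected in 12 of 14 LTiP cells (85.7%, 57.2 to 98.2), against 17.4% and 30.4% of aLP cells. Rora and Id2 were each detected in 9 of 14 (64.3%), against 2.2% and 12%. Lat was detected in 64.3% against 2.2%, and Il18r1 in 57.1% against 10.9%. The median difference of the 12 ILC precursor factors was 19.6 points, at percentile 99.8 among random lists, with 9 factors higher and 2 lower. The mean difference was 27.7 points, and 25.9 without the gate gene Zbtb16. Zbtb16 was detected in 7 of 14 LTiP cells (50.0%, 23.0 to 77), although the gate was PLZF-negative, against 3.3% of aLP cells. Lower in LTiP were Tsc22d3 (50.0% against 96.7%), the proto-oncogene Myc (21.4% against 65.2%), Igfbp4 (7.14% against 46.7%) and Rbpj, the DNA-binding partner of Notch (57.1% against 90.2%). Tbp was at 21.4% against 51.1%, Tle4 at 42.9% against 70.7%, Pira11 at 14.3% against 38% and Irf8 at 57.1% against 79.3%. For Rbpj, Tbp, Tle4, Pira11 and Irf8 the intervals of LTiP and aLP overlapped. Cd27 and H19 were detected in 0 of 14 LTiP cells (exact interval 0 to 23.2%), against 22.8% (14.7 to 32.8) and 21.7% (13.8 to 31.6) of aLP cells, with overlapping intervals.

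The comparison of LTiP with ILCP set the LTi precursors against the PLZF-positive precursors of the other ILCs. LTi genes were again detected more often in LTiP. Lta was detected in 64.3% of LTiP cells against 8.89% of ILCP cells (3.9 to 16.8) and Cd4 in 42.9% (17.7 to 71.1) against 7.78% (3.2 to 15.4). Tnfsf11, the gene of RANK ligand, and Il23r were each detected in 4 of 14 LTiP cells (28.6%, 8.39 to 58.1) and in 0 of 90 ILCP cells, which allows up to 3.33%. Cxcr5 was detected in 85.7% against 45.6%. Over the 11 LTi genes the share was on average 22.5 points higher in LTiP, 8 genes being higher and 2 lower, and 20.7 points higher without Cxcr5. Their median lay at percentile 99.99 among random lists. Il7r was detected in 71.4% against 42.2%, Id2 in 64.3% against 35.6%, Lat in 64.3% against 37.8% and Il18r1 in 57.1% against 31.1%, with overlapping intervals for each.

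Genes detected less often in LTiP than in ILCP included Cd27, H19 and Hes1, each in 0 of 14 LTiP cells (exact interval 0 to 23.2%). In ILCP cells of sort 3 they were detected in 81.1%, 70.0% and 62.2%. Igfbp4 was detected in 1 of 14 LTiP cells (7.14%, 0.181 to 33.9), against 71.1% of ILCP cells. Sox4 was detected in 28.6% against 87.8% and Zbtb16 in 50.0% against 96.7%. Myc and Tbp were each at 21.4% in LTiP, against 63.3% of ILCP cells for both, and Tle4 was at 42.9% against 82.2%. The median difference of the ILC precursor factors was -9.29 points, at percentile 34.9 among random lists, with a mean of -8.5 points, and -5.08 without the gate gene Zbtb16. The median of the T lineage and Notch genes was -12.9 points, at percentile 17.4. The median of the cytokine receptors, 5.4 points, lay at percentile 98.5. LTiP cells gave 33.6 detected assays on average and ILCP cells of sort 3 gave 40.8. The mean Ct was higher in LTiP than in these ILCP cells for Actb (13.4 against 12.7), Gapdh (15.2 against 14.1) and Hprt (17.7 against 16.3). Whether less cDNA in LTiP cells lowered their shares was not tested.

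With only 1 LTiP pool, limma over all 5 pools rests on the assumption that this pool varies like the others. With the sort as a block it passed 0 of 93 assays in either comparison (19 against aLP and 22 against ILCP at an unadjusted p under 0.05). Without the block 13 passed against aLP and 8 against ILCP.

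**Figure D3:**
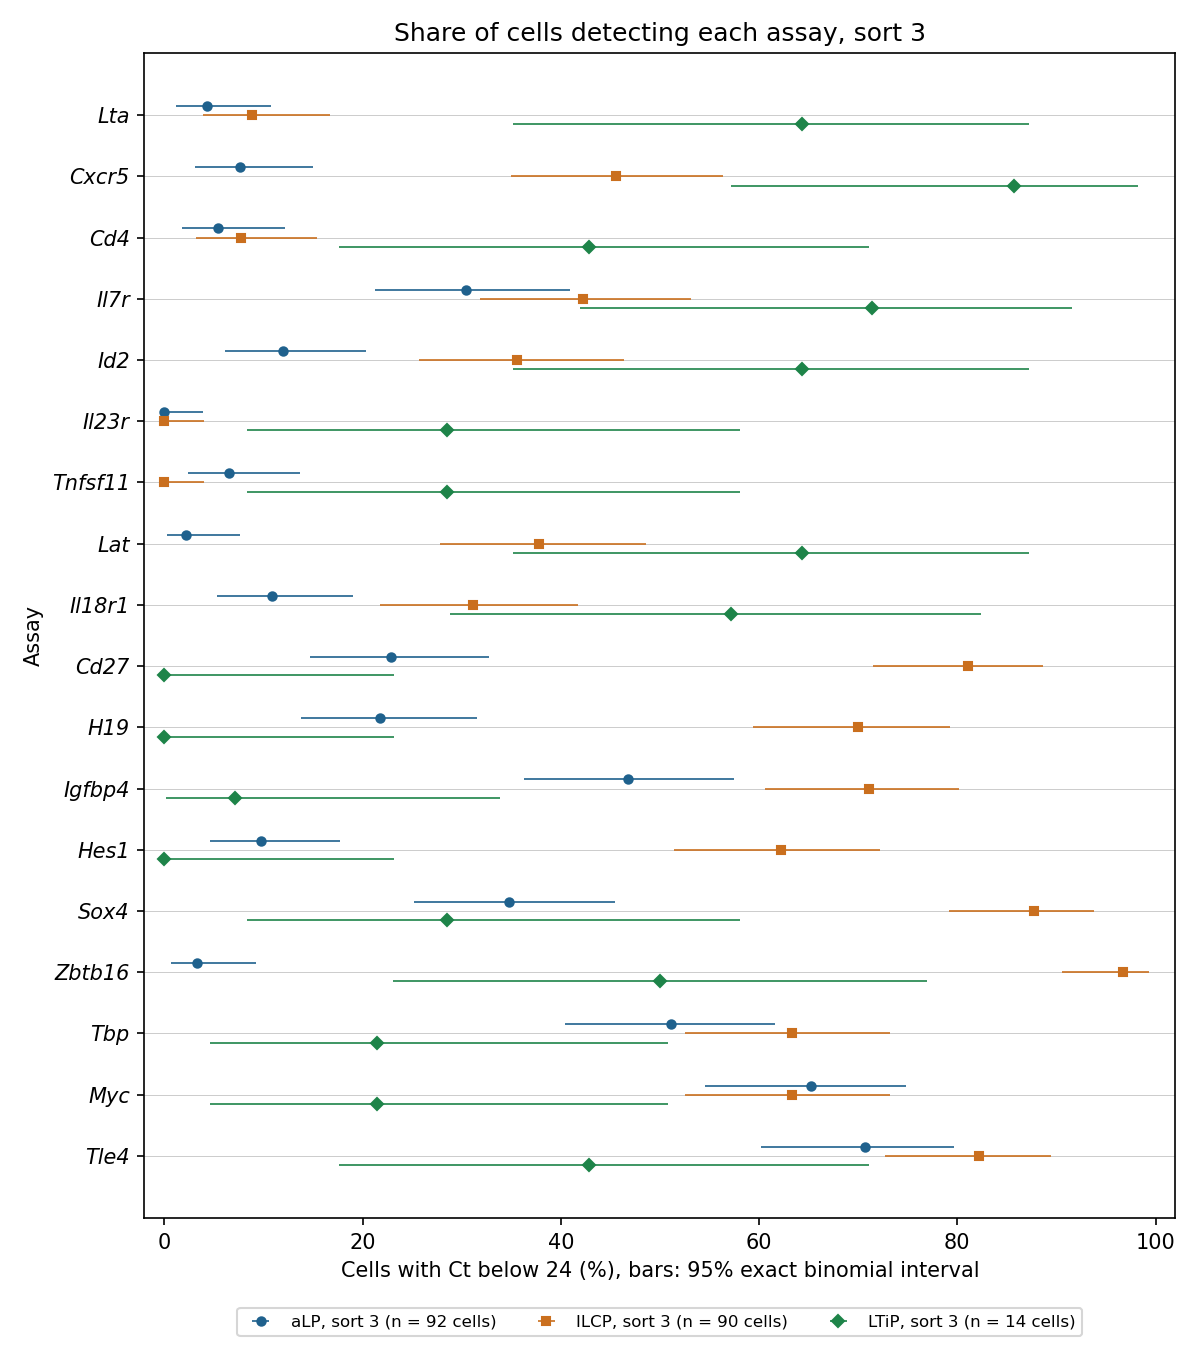
Percent of sort 3 cells with a Ct below 24 in aLP, ILCP and LTiP for 9 assays with large positive and 9 with large negative differences between LTiP and ILCP. Points are shares and bars 95% exact binomial intervals over cells. Lta lies at 64.3% in LTiP, 8.89% in ILCP and 4.35% in aLP, and Cd27 at 0, 81.1% and 22.8%.

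Detection of 2 genes in the same cell was counted for pairs fixed before the data were examined, and set against the product of the single shares. The exact intervals are those of the joint share alone. They do not test independence, and a product inside the interval does not show it. Zbtb16 and Cxcr5 were found together in 38.7% and 45.6% of ILCP cells (36.2% and 44% from the products, inside the exact intervals). In LTiP they were together in 7 of 14 cells (50.0%, against 42.9% from the product). Tcf7 and Zbtb16 were detected together in 85.5% and 95.6% of ILCP cells, against 83.0% and 93.4%. Where a gene is in nearly every cell, as Zbtb16 and Tcf7 are in ILCP, the joint share can hardly differ from the product. Values near the product then do not tell whether the genes are detected independently.

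For the other pairs given here, the shares of doubly detected cells in both ILCP pools had exact intervals that held the product of the single shares. For the pairs with Tcf7 or Tox, which were also in nearly every ILCP cell, this was almost fixed in advance. Gata3 was detected together with Tbx21 in 11.3% and 3.33% of ILCP cells (12% and 4.67% from the products). Tcf7 was detected with Gata3 in 35.5% and 30% (32.9% and 29%) and with Id2 in 32.3% and 34.4% (32.9% and 34.4%). Il2rb was found with Il17rb in 6.45% and 4.44% (7.54% and 6.58%), and with Il1rl1 in 1.61% and 3.33% (8.30% and 2.53%). In sort 2, Il1rl1 and Il2rb were thus together in 1 of 62 ILCP cells, with Il1rl1 alone in 10 and Il2rb alone in 28. Whether this pair avoids the same cell was not tested. Tox and Nfil3 were detected together in 54.8% and 42.2% of ILCP cells, against 54.8% and 41%. In aLP cells 3 of the pairs given here were found together more often than their products, which lay below the exact intervals. Tcf7 and Zbtb16 were together in 14.8% (6.62 to 27.1) of sort 2 cells against 6.41%, and in 3 of 92 sort 3 cells (0.678 to 9.24%) against 0.567%. In sort 3, Tox and Nfil3 were together in 42.4% (32.1 to 53.1) against 30.7%, and Zbtb16 and Cxcr5 in 2 of 92 cells (0.264 to 7.63%) against 0.248%. Single aLP cells gave 8 to 45 detected assays in sort 2 and 18 to 47 in sort 3. Such uneven detection can raise the joint share of any pair, and its part here was not tested.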

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

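The settings that use Actb, Gapdh and Hprt alone and the one that leaves out aLP cells with Zbtb16 were chosen after the data had been seen. The other alternatives were fixed before. The 6 assays called for ILCP against aLP became 12 with a detection limit of 26, 16 with 28, 17 with no limit, 11 with a 20% assay filter and 16 with linear averaging, and each of these lists held all 6. The count was 20 with the logit of shares (5 shared, without Irf8). With detected cells only, limma passed 0 of 55 assays, with 10 at an unadjusted p under 0.05. With the sort as a replicate block 2 passed, Zbtb16 and Rora. For ILCP against aLP, apart from the 4 assays and the 1 gene group lost, the block changed no call among the named assays and groups. Leaving out 1 pool leaves the spread of an assay, before moderation over assays, to the 2 pools of the other group alone, so counts of calls are not compared here. The other settings gave 5 to 9 calls and kept all 6, except scaling to housekeeping assays, which gave 5 without Irf8. That scaling includes Tbp, which gave no Ct in any aLP cell of sort 2. Scaled on Actb, Gapdh and Hprt alone, Irf8 passed (limma, adjusted p = 0.0266). No call changed direction. Scaling on Actb, Gapdh and Hprt lowered the median difference over all assays from 0.54 to 0.38. Apart from the smaller sets of pools and assays, the cause was not tested. Requiring every housekeeping assay left 0 aLP cells of sort 2 and gave no value.

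The 1 gene group called, the T lineage and Notch genes, was not called with scaling to housekeeping assays (adjusted p = 0.0952), where the ILC precursor and ILC2 groups passed instead (0.0342 each). That scaling includes Tbp, which gave no Ct in any aLP cell of sort 2. The T lineage and Notch group stayed called among 4 with a limit of 28 (ILC precursor, ILC2, and ILC1 and NK groups added). With scaling on Actb, Gapdh and Hprt it was among 4 (ILC precursor, ILC2 and B lineage groups added), and without aLP cells with Zbtb16 among 5. Of these, the gate genes and the ILC precursor factors contain Zbtb16, whose aLP level that filter sets to 0. The number of groups called was 0 with the replicate block (3 unadjusted in fry), 0 in matched cells (3 unadjusted) and 0 with camera (0 unadjusted). The mean LTi gene difference of LTiP was 13 points against aLP and 8.29 against ILCP with every housekeeping assay detected, which left 3 LTiP cells. Other settings gave 29.6 to 32.8 and 22.5 to 25.8 points, among them cells numbered 1 to 96 (31.5 and 23.0). The share of assays with 1 sign in both sorts was 73.3% to 79.3%. Of the co-detection shares under other limits 249 stayed within their interval and 11 did not.

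Of 37 named assays 7 changed sign, none of them called. With detected cells only Cxcr5 was at -0.022 and Id2 at -0.024, and with a limit of 22 Id2 was at -0.0032. Scaling on Actb, Gapdh and Hprt gave Itga4 -0.31, Actb -0.20 and Gapdh -0.13, and matching gave Itga4 -0.28, Actb -0.13 and Gapdh -0.0067. Itga4 was at -0.040 with median scaling. On the logit scale Itga4 was at -0.97 and Il1rl1 at -0.12. Without 1 pool, Il7r ran from -0.78 (aLP of sort 3 left out) to 1.38, with -0.37 without ILCP of sort 2. Il1rl1 ran from -0.19 (ILCP of sort 2 left out) to 0.62, Gapdh from -0.045 (aLP of sort 3 left out) to 1.08, and Itga4 from -0.082 (ILCP of sort 3 left out) to 0.51. The cause was not tested. With 14 LTiP cells a share below 23.2% can go unseen.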

Other observations

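The tests of technical explanations in this part, and the genes and pairs of the next paragraphs, were chosen after the values had been seen. Adjusted p values and calls for ILCP against aLP are those of the planned fit, except in matched cells.

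Of 3 imprinted genes noted on the panel (H19, Igf2 and Cdkn1c), none passed for ILCP against aLP. Cdkn1c, a growth-restraining cell cycle inhibitor, was detected in 33.9% and 40.0% of ILCP cells of sorts 2 and 3, in 29.6% and 13% of aLP cells and in 1 of 14 LTiP cells, and its LTiP and ILCP intervals overlapped, as did those of Igf2 (0 of 14 LTiP cells). H19 and Igf2, neighbours in 1 imprinted domain that are expressed from opposite parental copies, were detected together in 12.9% and 22.2% of ILCP cells. The products of their single shares are 10.5% and 19.4%, inside the exact intervals of 5.74 to 23.9% and 14.1 to 32.2%, which do not test independence. For 2 other pairs the product lay outside the interval in 1 pool each: Igf2 with Cdkn1c in ILCP cells of sort 3 (4.44%, 1.22 to 10.99, product 11.11%), and H19 with Cdkn1c in aLP cells of sort 2 (20.4%, 10.6 to 33.5, product 10.4%). The part of uneven detection over aLP cells in the higher joint share of H19 with Cdkn1c was not tested.

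Tnfrsf9, which encodes the co-stimulatory receptor 4-1BB, was detected in 51.6% and 40.0% of ILCP cells, in 0 of 54 and 1.09% of aLP cells, and in 21.4% of LTiP cells, with overlapping ILCP and LTiP intervals. Its difference was 1.11 ± 0.23 cycles (limma, adjusted p = 0.0700). Fgf15 was detected in 8.06% and 20% of ILCP cells and in 0 of 54, 0 of 92 and 0 of 14 cells of aLP and LTiP. The co-repressor gene Tle3 differed by 0.78 and 1.54 cycles between ILCP and aLP in the 2 sorts, where its relative Tle1 differed by -2.29 and -2.34. Spon2 was detected in 35.7% of LTiP cells, in 12.2% of ILCP cells and in 0 of 92 aLP cells of sort 3, with overlapping LTiP and ILCP intervals.

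Some ILCP minus aLP differences had opposite signs in the 2 sorts. They were -2.77 and 1.98 for Igfbp4, -1.05 and 3.7 for Sox4, and -0.52 and 2.2 for Bcl2.

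Zbtb16 was detected in 50.0% of LTiP cells and 20.4% of aLP cells of sort 2, both sorted as PLZF-negative. ILCP cells in these pools would bring Cd27, H19, Hes1, Rora and Tcf7, assays in at least 50% of ILCP and under 25% of aLP cells of sort 3. The Zbtb16-detected cells held 46.4% (LTiP, 7 cells) and 54.9% (aLP, 11 cells) of the detections in as many ILCP cells. Draws of ILCP cells gave 78.6 to 118% and 76.9 to 120.8%. In LTiP these were Rora (6 cells) and Tcf7 (7), frequent in LTiP as a whole (64.3% and 85.7%), with Cd27, H19 and Hes1 in 0. Zbtb16-detected ILCP cells of sort 3 held Cd27, H19 and Hes1 in 83.9%, 71.3% and 64.4%. In aLP they were Tcf7 (8), Cd27 (6), H19 (3), Rora (3) and Hes1 (0). Cd27 did not mark ILCP in sort 2, at 62.9% of ILCP and 59.3% of aLP cells. Background of the Zbtb16 assay would give LTiP the share of aLP cells of the same sort, whose upper limit of 9.23% lies below the LTiP lower limit of 23.0%. In aLP cells of sort 2, background unrelated to a cell's cDNA would not follow Tcf7. Tcf7 was in 72.7% of Zbtb16-detected cells (39 to 94) and 20.9% of the others (10 to 36). However, these aLP cells gave 8 to 45 detected assays each, so a background that rises with cDNA could follow Tcf7 too. All 14 LTiP cells were numbered below 97, as were only 24 of the 92 aLP cells of sort 3. A background tied to the number range was therefore not tested for LTiP. Stray ILCP cells alone thus did not account for the detections in either pool. In aLP cells of sort 2, a background unrelated to cDNA did not either, while one that rises with cDNA was not tested. For LTiP, the values speak only against a background shared by all cells of the sort. A few stray ILCP cells among the Zbtb16-detected cells stay open, though in LTiP each would have to lack Cd27, H19 and Hes1. The 3 Zbtb16-detected aLP cells of sort 3 stay open too. A hypothesis left open, without protein values to test it, is that some cells may transcribe Zbtb16 below the level the PLZF gate reads. The median level of the Zbtb16-detected cells differed by -2.36 (LTiP) and -1.56 (aLP) cycles from that of Zbtb16-detected ILCP cells of the same sort. However, 2 of the 7 LTiP and 6 of the 11 aLP cells lay at or above the 10th percentile of those ILCP cells. A lower transcript level thus did not mark every one of them.

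More assays were detected in ILCP than in aLP cells, and 79.1% of the differences were positive. Higher RNA recovery in ILCP cells is a candidate explanation, since their mean Hprt Ct was lower in both sorts, although the mean Actb Ct in sort 3 was not (12.7 in ILCP and 12.6 in aLP). In 198 cells matched within sorts on the Ct of Actb, Gapdh and Hprt, the 6 called assays kept a median of 106% of their difference (97.4 to 120%) and all 6 passed again. This was almost fixed in advance and does not weigh on recovery. Actb, Gapdh and Hprt differed by at most 1.22 cycles in a sort, the called assays by 2.21 to 7.10 in size, and Irf8 was lower in ILCP. In the matched cells 72.8% of differences were positive (exact interval over assays, which are not independent, 62.6 to 81.6), with 40.9 and 31.4 assays detected in ILCP and aLP cells. Recovery as these assays read it therefore did not account for the whole pattern, while the median difference fell to 0.38 and a part of it stays open, as does a broader transcription in ILCP cells, which was not tested.

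Tbp gave no Ct in any of 55 aLP cells of sort 2. A lack of Tbp transcripts in aLP cells would show in sort 3 too, where 52.2% of aLP cells had a Tbp Ct (41.5 to 62.7). In sort 2, Tbp had a Ct in 59.6% of the ILCP cells numbered 1 to 96 (45.1 to 73) and in 0 of the 10 numbered 97 or higher (0 to 30.9), the range that holds all aLP cells of that sort. This is consistent with no working Tbp readout for sort 2 cells numbered 97 or higher. Of 39 assays with a Ct in at least 50% of the ILCP cells numbered 1 to 96, Tbp was the 1 assay without any Ct in those 10 cells.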
